A study of Homo sapiens with 4 samples.

How the data were processed

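Expression was measured on 4 Affymetrix whole-transcript arrays, all labelled as HGC27 cells, an established human gastric cancer line grown in culture. One array is labelled as untreated cells, one as cells infected with an empty lentiviral vector, and one each as cells infected with hairpin A or hairpin B against SNAI1, the gene of the transcription factor SNAIL. These names are the submitters' labels, and the source of the RNA on each array was not established here. Infected cells were selected with puromycin, per the labels' protocols. The titles number the first pair as replicates of a control group and the second pair as replicates of a knockdown group, and these 2 groups of 2 were compared. The members of a group differ in treatment, so the spread within a group holds that difference as well. Nothing in the labels says whether arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

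The deposited values are log2 expression values per probe set, and per the submitters' processing notes they were made with RMA and Affymetrix Power Tools, with versions not given in the sources used here. RMA subtracts background, normalizes the arrays to a common distribution and summarizes probes on the log2 scale. The quartiles of the 4 arrays were close but not identical, with medians of 3.45 for untreated cells, 3.46 for the empty vector, 3.49 for hairpin A and 3.43 for hairpin B over 53617 probe sets. A normalization of this kind removes a shift shared by most genes. Where a gene lay below the median gene in a group, its signal was not shown to exceed background, and its difference from a higher level is a lower limit. The number of arrays limits the precision.

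Gene names came from the platform annotation, which gave 1 symbol to 16098 probe sets, several symbols to 0, and left 37519 unnamed here. All 16098 symbols matched the gene table of assembly GCF_000001405.40 (GRCh38.p14) through their gene identifiers. That table was used only for names and for which genes neighbour each other. Where a gene had more than 1 probe set, as 779 did, the one with the highest mean over the 4 arrays was used, which left 14884 genes. No filter on dim probe sets was applied. Genes the annotation did not name, CDH1 and CDH2 among them, were not analysed here.

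The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Each knockdown array was also set against both controls in the same way, which assumes that the lone array varies like the controls. Gene lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over the 28 lists tested. Camera with an estimated correlation and fry take their precision from the few arrays, so they can hardly call any list here. A list they did not call is not shown to be unchanged. The comparison was also described without a test, by counting genes whose groups did not overlap and lay at least 1 log2 (2-fold) apart. Single arrays were compared by the number of genes differing by at least 2-fold, and by each list's median with its percentile among 10000 random lists of equal size matched on mean level. Random lists hold unrelated genes, so a list whose members vary together reaches an extreme percentile more easily. Shared controls were allowed for by 100 simulations of unchanged arrays. Figures and gene-order calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

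The steps were tested on simulated data, in which 200 of 14884 genes were changed. With each gene's spread drawn from the distribution limma fitted to this comparison, 0% of genes changed by 1 log2, 8% of those changed by 2 log2 and 80% of those changed by 4 log2 were called. For 1 array against both controls, with spreads drawn from that of the controls, 16% of genes changed by 1 log2, 100% of those changed by 2 log2 and 0.143% of unchanged genes were called. With the moderated spreads, which vary less between genes, the shares were higher, with 80% of genes changed by 2 log2 called in the group comparison and 96% of those changed by 1 log2 called for 1 array. These shares hold for 200 changed genes. With fewer changed genes the adjustment is stricter, so larger changes can be missed as well. A count of 0 therefore does not show that changes of 2-fold or more were absent.

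The tests, the 30 gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where stated. The lists held 881 distinct genes, of which 499 were measured. Integrins and laminins, and replication-dependent histones, had 0 measured members and were not tested. The result of 1 further list is not reported here. The rule named SNAI1 and the transcription factors of the epithelial-mesenchymal transition (EMT), and the 10 genes with the largest rise and fall among those past the threshold. Where fewer passed, it filled the places by the size of the gap between groups and then by the moderated statistic. It also named up to 4 members of each list by size of change, and the 5 genes with the largest difference in each direction between single arrays. MicroRNA, small nucleolar RNA, olfactory receptor, LOC and LINC genes were counted but not named. Any other gene was named after its values were seen, as were all neighbouring genes and markers of another cell line. The alternatives were a repeated quantile normalization, median centring, a filter on dim genes, the mean of all probe sets, a variance trend, array weights, a replicate block, and leaving out each array in turn.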

Results

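The study asked how gene expression in HGC27 gastric cancer cells differs when SNAI1, which encodes a zinc-finger repressor that drives the epithelial-mesenchymal transition, is targeted by short hairpin RNA. There were 2 control arrays, labelled as untreated and empty-vector cells, and 2 knockdown arrays, labelled as hairpin A and hairpin B. All values are deposited log2 expression values, in which 1 unit is 2-fold, and the median gene lay at 4.58.

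SNAI1 itself was measured by probe set 16914791. Its level was 5.83 in untreated cells and 5.85 with the empty vector, against 4.67 on the array labelled shRNA-A and 5.67 on the array labelled shRNA-B. Set against both controls, SNAI1 fell on the array labelled shRNA-A by 1.17 ± 0.18 (SE; 1 array against 2; limma adjusted p = 0.017), which left 44.5% of the control signal, background included. With hairpin B the difference was -0.16 ± 0.18 (SE; adjusted p = 0.97), or 89.2% of the control signal, and did not pass the test. Over both hairpins the difference was -0.67 ± 0.38 (SE, n = 2 per group; adjusted p = 0.92). The lower mean of the knockdown group therefore came mainly from 1 array. That array also differed from the others in many other genes, so its lower SNAI1 is not shown to be the hairpin's effect.

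The array labelled shRNA-A stood apart from the other 3 arrays. Across genes, which are not independent replicates, its Spearman rank correlations with them were 0.932 to 0.934, while those among the others were 0.987 to 0.990. Against both controls 2024 of 14884 genes passed the test on that array, 1049 higher and 975 lower, and 1510 of them differed by at least 2-fold. For the array labelled shRNA-B 0 genes passed in limma, with 700 at an unadjusted p under 0.05. That count does not show that 2-fold changes were absent, as CD24 differed there by -1.83 ± 0.19 (SE) with adjusted p = 0.961. In the comparison of both hairpins with both controls 0 genes passed, with 264 at an unadjusted p under 0.05 and a smallest adjusted p of 0.92. The members of the gene groups that follow are therefore given mainly for the array labelled shRNA-A, and the plot of list medians shows both arrays. Because so many genes passed on that array, a list can hold such members whatever its theme. The counts of members were not tested against that overall share. In these groups, fell and rose mean lower and higher than the control mean. The RNA on that array may come from other cells, as described below, so such differences are not shown to be regulation within HGC27 cells.

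Among the EMT transcription factors, PRRX1, TWIST1, ZEB1, TCF3, TCF4 and TCF12 were lower on the array labelled shRNA-A than in the controls. SNAI1 was lower there too, and GSC was higher. PRRX1 fell there by 4.09 ± 0.19 (SE), TWIST1 by 2.97 ± 0.20, TCF4 by 1.77 ± 0.19, TCF12 by 1.71 ± 0.18, TCF3 by 1.66 ± 0.19 and ZEB1 by 1.38 ± 0.19, and GSC differed by 1.19 ± 0.23. Of the 17 measured members, 7 fell and 1 rose adjusted over all genes, and 9 fell and 3 rose adjusted over the list alone. ZEB2 (-0.54), SOX4 (-0.72), SOX9 (0.70), TWIST2 (0.75), HMGA2 (0.31), KLF8 (-0.32), SNAI3 (-0.37), FOXF1 (0.05) and SNAI2 (-0.03) did not pass over all genes. Members passing numbered 0 on the array labelled shRNA-B, where SNAI2, a paralog of SNAI1, differed from the controls by 0.70 (adjusted p = 0.96). As a list these genes were lower on the array labelled shRNA-A (camera adjusted p = 0.0023). With an estimated correlation the list was not called, but that test can hardly call any list from so few arrays. The same limit holds wherever an estimated correlation is given below.

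**Figure D1:**
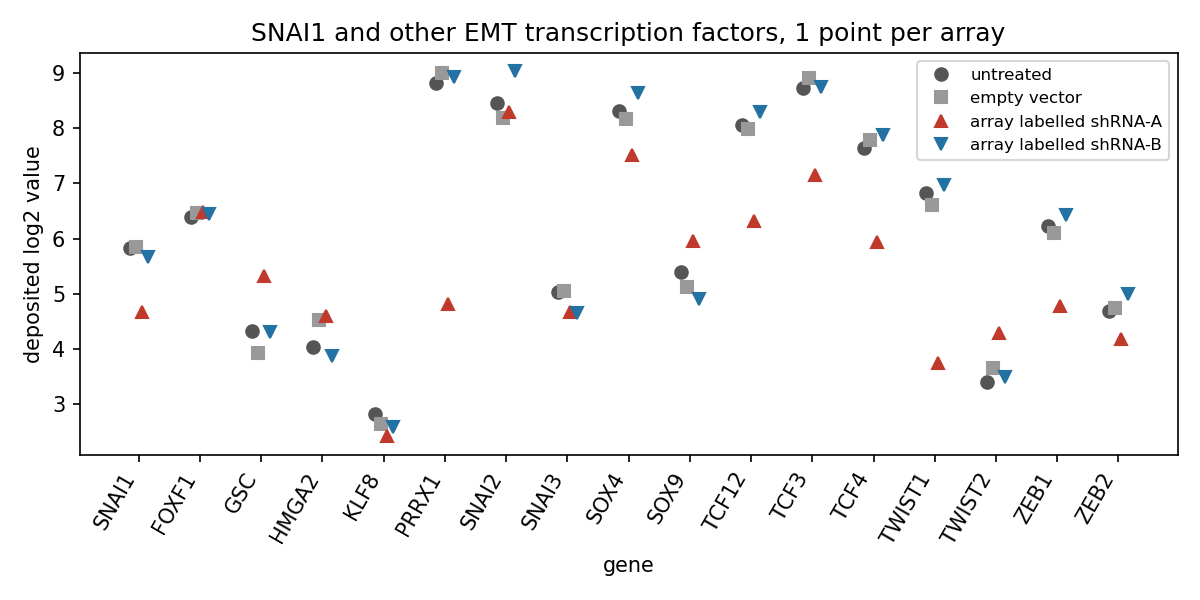
Deposited log2 values of SNAI1 and the other measured EMT transcription factors, 1 point per array. SNAI1 was at 4.67 on the array labelled shRNA-A and between 5.67 and 5.85 on the other 3, and PRRX1 was at 4.81 against 8.82 to 8.99.

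Mesenchymal marker genes included 8 members that fell and 0 that rose, of 13 measured, on the array labelled shRNA-A, and 9 that fell adjusted over the list alone. LUM, a matrix proteoglycan, was at 4.30 there and at 10.79 to 10.99 elsewhere, a fall by 6.59 ± 0.20 (SE). The related proteoglycan DCN fell by 4.06 ± 0.20, the intermediate filament gene VIM by 1.93 ± 0.20, and fibronectin, FN1, by 1.82 ± 0.36. The list was called lower on that array (camera adjusted p = 7.14e-08), with adjusted p = 0.876 with an estimated correlation. With hairpin B 0 passed, and LUM differed by -0.03, DCN by 0.11, VIM by -0.09 and FN1 by -0.17. Over both hairpins the list had a median of -0.83 and was called lower by camera (adjusted p = 0.00044), but with adjusted p = 0.891 with an estimated correlation and 0.795 without the array labelled shRNA-A. No member passed singly in that comparison.

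Epithelial junction and keratin genes included 9 members that rose and 1 that fell, of 31 measured, on the array labelled shRNA-A, with the same counts adjusted over the list alone. The desmosome and junction genes JUP (2.55 ± 0.23 SE), DSP (2.30 ± 0.39) and OCLN (2.05 ± 0.21), and CDS1 (1.66 ± 0.24), rose. Hairpin B gave 0 members past the test, and the corresponding differences were -0.06, 0.09, 0.36 and 0.51. The list was not called on the array labelled shRNA-A (camera adjusted p = 0.054) or over both hairpins (0.171). Of 13 measured genes reported as repressed by SNAI1, 3 rose (OCLN, DSP and the keratin gene KRT18, by 1.48 ± 0.18) and 1, the cyclin gene CCND2, fell by 2.65 ± 0.19 on that array. The list test gave an adjusted p of 0.944 there and 0.81 over both hairpins.

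Matrix proteases and their inhibitors fell on the array labelled shRNA-A in 4 of 19 measured cases, adjusted over all genes, and in 5 adjusted over the list alone. The membrane-type protease MMP14 fell by 4.02 ± 0.26 (SE), MMP16 by 3.26 ± 0.20 and TIMP2 by 2.04 ± 0.18, and MMP15 was at 5.05 against 6.51 and 6.59 in the controls (adjusted p = 0.0095). The corresponding differences on the array labelled shRNA-B were 0.03, 0.01, 0.18 and -0.33. Of 18 Wnt/beta-catenin targets 8 fell and 0 rose, or 9 and 1 adjusted over the list alone. They included the feedback inhibitor AXIN2 (-2.84 ± 0.19), CD44 (-2.60 ± 0.20), MYC (-1.96 ± 0.25) and CCND1 (-1.71 ± 0.19). Camera called the Wnt list lower on that array (adjusted p = 0.00062), and its adjusted p = 0.876 with an estimated correlation. Of 12 YAP/TAZ targets AXL and DOCK5 fell by 1.82 ± 0.22 and 1.58 ± 0.18 and FOXF2 rose by 1.29 ± 0.21, while IGFBP3 (-0.79) did not pass. Of 13 TGF-beta response genes 2 fell, THBS1 among them by 1.49 ± 0.20, and KLF10 (0.61), SKIL (0.76) and SKI (-0.69) did not pass.

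**Figure D2:**
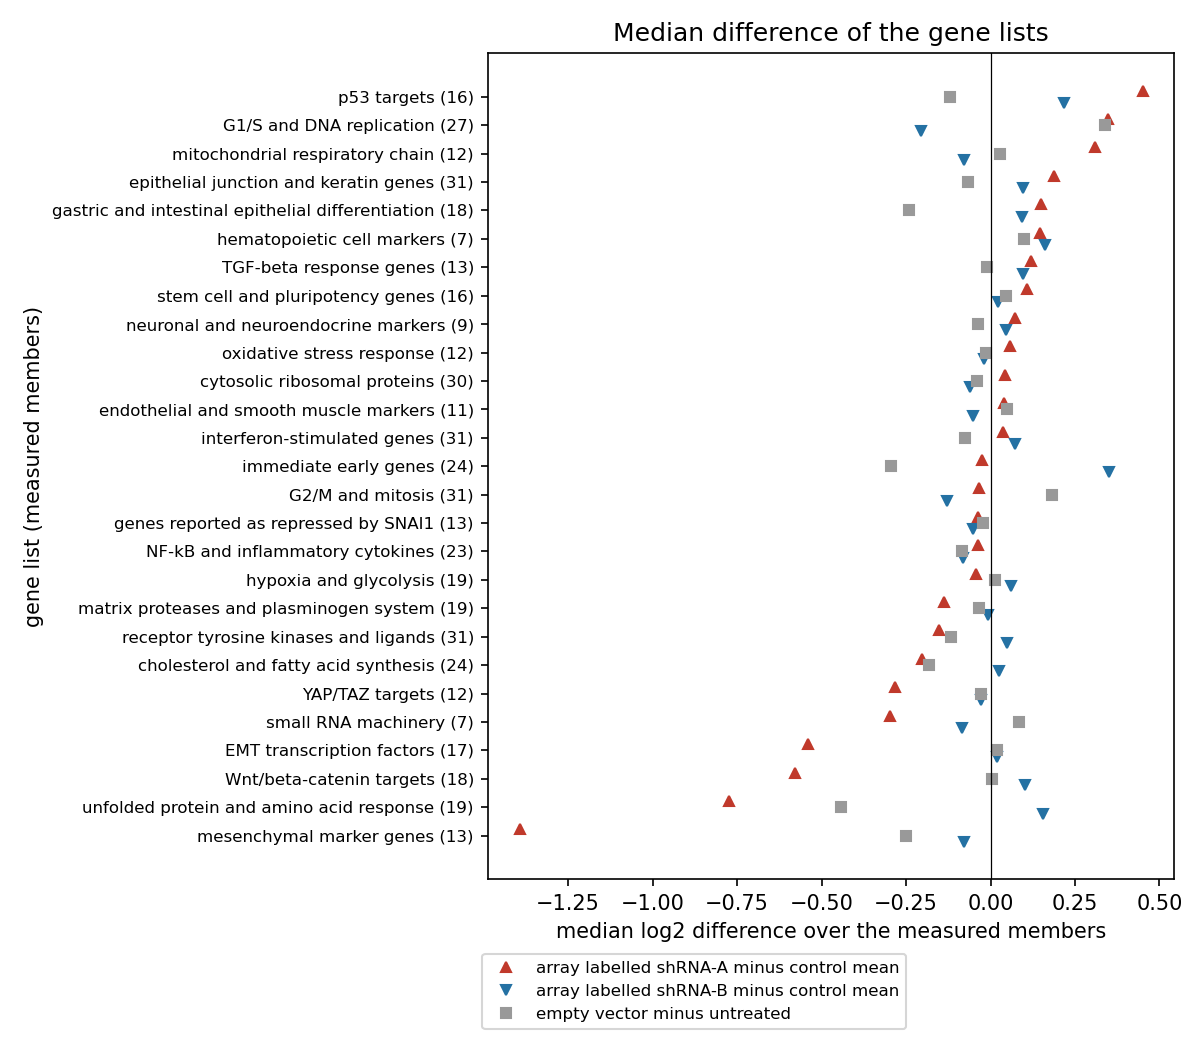
Median log2 difference of the gene lists reported here, with the number of measured members in parentheses, for each knockdown array against the mean of the controls and for the empty vector against untreated cells. The mesenchymal list lay at -1.39 on the array labelled shRNA-A and at -0.08 on the array labelled shRNA-B.

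Cell cycle and stress genes were mixed. On the array labelled shRNA-A 4 of 27 genes of G1/S and DNA replication rose and 0 fell, among them CCNE1 (1.87 ± 0.20 SE), CDC25A (1.73 ± 0.32) and GINS2 (1.40 ± 0.25), while GINS4 (1.16) did not pass. The list was called higher there (camera adjusted p = 0.0192) and lower on the array labelled shRNA-B (adjusted p = 0.00831). Neither was called with an estimated correlation, a test that can hardly call a list from so few arrays. On the array labelled shRNA-B the list's median was -0.33 relative to the empty vector and 0.0036 relative to untreated cells. Genes of G2/M and mitosis were called lower on the array labelled shRNA-B (camera adjusted p = 0.00137), and that list had adjusted p = 0.918 with an estimated correlation. Its median there was -0.26 relative to the empty vector and -0.07 relative to untreated cells, and that of the empty vector relative to untreated cells was 0.18. Of its 31 members MKI67 (-1.33 ± 0.24) and NDC80 (-1.14 ± 0.23) fell and MAD2L1 (1.34 ± 0.22) rose on the array labelled shRNA-A, and CDC20 (-0.76) did not pass.

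Targets of p53 were called higher over both hairpins (camera adjusted p = 0.0212; median 0.31), with adjusted p = 0.891 with an estimated correlation. That call was also lost without the array labelled shRNA-A (adjusted p = 0.521) and without the empty vector (0.0839). The list's median was 0.45 on the array labelled shRNA-A and 0.22 on the array labelled shRNA-B. Of 16 measured members 3 rose on the array labelled shRNA-A, among them RRM2B, a ribonucleotide reductase subunit, by 1.38 ± 0.21 (SE), while PMAIP1 (1.18), ACER2 (1.11) and SESN2 (0.70) did not pass. Genes of the unfolded protein and amino acid response were called lower over both hairpins (camera adjusted p = 0.0212; median -0.36), also with adjusted p = 0.891 with an estimated correlation, 0.698 without the array labelled shRNA-A, 0.756 without untreated cells and 0.0545 among genes above the median level. Of 19 measured members 4 fell on the array labelled shRNA-A, adjusted over all genes, among them VLDLR (-2.31 ± 0.21), SEL1L (-1.80 ± 0.33) and HYOU1 (-1.12 ± 0.18). Its median was -0.77 on that array and 0.16 on the array labelled shRNA-B. Camera called it lower on the former (adjusted p = 0.000208), with adjusted p = 0.876 with an estimated correlation. Immediate early genes were called higher on the array labelled shRNA-B (camera adjusted p = 0.00048; median 0.35), with adjusted p = 0.918 with an estimated correlation, and EGR1 (0.73) and JUN (0.59) did not pass singly there. On the array labelled shRNA-A 1 of its 24 members, SPRY2, rose by 1.14 ± 0.19 and 3 fell, MYC among them.

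Receptor tyrosine kinases and their ligands moved both ways on the array labelled shRNA-A, where 5 of 31 rose and 8 fell. KIT rose by 3.98 ± 0.20 (SE) and FGF2 by 3.45 ± 0.18, and the collagen receptor DDR2 fell by 3.57 ± 0.31 and ROR2 by 3.06 ± 0.18. Of 16 stem cell and pluripotency genes 3 rose, including LIN28B (3.61 ± 0.24) and SOX2 (2.38 ± 0.18), and 5 fell, including CD24 (-2.13 ± 0.19) and CD44. Of 31 interferon-stimulated genes 3 rose, among them HERC5 (3.23 ± 0.21) and HERC6 (1.53 ± 0.21), and 4 fell, among them IFI44L (-4.33 ± 0.21) and IFITM3 (-1.76 ± 0.19). Of 23 NF-kB and inflammatory genes 2 fell, the chemokine CCL2 by 4.42 ± 0.32 and NFKB2 by 1.20 ± 0.22, and IL11 (-0.61) and CXCL3 (-0.64) did not pass.

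In hypoxia and glycolysis 2 of 19 members rose on the array labelled shRNA-A, BNIP3 by 5.18 ± 0.18 (SE) and NDRG1 by 1.49 ± 0.19, and 3 fell, LOX (-2.20 ± 0.20) and VEGFA (-1.56 ± 0.29) among them. In cholesterol and fatty acid synthesis 7 of 24 fell, including SQLE (-2.51 ± 0.19), ACACA (-1.51 ± 0.19), SREBF1 (-1.34 ± 0.18) and FASN (-1.19 ± 0.24). In gastric and intestinal differentiation 1 of 18 rose, SOX2, while FOXA1 (0.89), CDX2 (0.91) and VIL1 (0.36) did not pass. Members passing numbered 0 of 12 for oxidative stress (GSR differed by -0.67), 0 of 30 for ribosomal proteins (RPS9, -0.58), 0 of 12 for the respiratory chain (COX5A, 0.67) and 0 of 11 for endothelial and smooth muscle markers (KDR, -0.70). Among hematopoietic markers CD68 rose by 0.91 ± 0.19, 1 of 7 measured. Among neuronal and neuroendocrine markers INSM1 rose by 1.29 ± 0.19 and 2 of 9 fell, NCAM1 among them by 1.19 ± 0.21. In the small RNA machinery TNRC6B fell by 0.90 ± 0.18, 1 of 7.

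Over both hairpins camera called 3 of 28 lists, mesenchymal markers, p53 targets and the unfolded protein response, and the other 25 had adjusted p between 0.138 and 0.996. With an estimated correlation, and with fry, 0 lists were called, but these tests can hardly call any list from so few arrays. On the array labelled shRNA-B 0 genes of any list passed adjusted over all genes, and adjusted over the list alone 1 did, CD24. CD24 was also the only list gene to pass over both hairpins adjusted over the list alone, with 0 adjusted over all genes. The list's median, mean and test differed in sign over both hairpins for SNAI1-repressed genes, TGF-beta response, hypoxia, oxidative stress and ribosomal protein genes.

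Few genes lay beyond both controls by at least 2-fold on both knockdown arrays. With a gap of at least 1 log2 there were 7 genes, 2 higher and 5 lower, of which 2 of the lower were microRNA genes. CD24, a surface glycoprotein, was at 5.95 and 6.12 in the controls and at 3.90 and 4.20 with hairpins A and B, and CCN3, a secreted matricellular protein, was at 8.54 and 8.69 against 4.11 and 7.13. CACHD1 was at 5.56 and 5.53 against 7.65 and 6.57. The chemokine CCL7 (1.34 and 1.45 against 2.75 and 2.81) and the pseudogene RPL23AP32 (4.01 and 3.99 against 2.19 and 2.46) lay below the median gene. CD24 and RPL23AP32 have near-identical copies elsewhere in the genome, so their probe sets are uncertain. None of these passed the limma test over both hairpins (adjusted p = 0.92 for each).

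The other 2 ways of splitting the 4 arrays into pairs gave 3 and 14 genes with such a gap, so 7 was not the highest count. Groups did not overlap at all for 30.8% of genes, against 30.5% and 36.9% for the other splits. The rule further named NDRG1, a stress-responsive gene (1.19 ± 0.26 SE over both hairpins), ZNF501, CR1L, CCKAR, ZNF396, SPPL2C, REM2 and ADD3 with higher means. It named RRBP1, a ribosome-binding protein of the endoplasmic reticulum (-1.09 ± 0.24), SND1-IT1, FSTL5, ASAH2, FSCB, ZNF285 and the imprinted antisense transcript KCNQ1OT1 (-1.26 ± 0.33) with lower means. All had adjusted p = 0.92.

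Hairpin A and hairpin B are labelled as targeting the same gene, and their arrays were compared directly, 1 array each and so without a test. IRS4, an insulin receptor substrate, was 7.13 higher on the array labelled shRNA-A, TFCP2 5.26, RADX 5.23, BNIP3 5.12 and POPDC1 4.94. On the other 3 arrays these 5 genes lay at 3.63 or lower, below the median gene and not shown to be above background, so the differences are lower limits and their order is uncertain. LUM was at -6.57 relative to the array labelled shRNA-B, the proteoglycan BGN at -6.02, BMP5 at -5.83, the imprinted gene PEG10 at -5.75 and TRPS1 at -5.63. All of these but BGN lay below the median gene on the array labelled shRNA-A, which limits their differences in the same way. At least 2-fold differences numbered 1789, 864 higher and 925 lower with hairpin A. List medians were lowest for mesenchymal markers (-1.24), the unfolded protein response (-0.97) and Wnt targets (-0.86), each below all of 10000 random lists, and highest for G1/S genes (0.62), above all of them.

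The hairpins' differences were also set against each other across genes. Relative to the shared empty vector they correlated at Pearson's r = 0.14, with a covariance of 0.0321. Simulated unchanged arrays sharing a control had a covariance of 0.0303 and an r of 0.50. The simulation gave both arrays the spread of the controls. The real differences from the empty vector had SDs across genes of 0.73 for hairpin A and 0.32 for hairpin B. The simulated r therefore cannot be set against 0.14, and only the covariances can be compared. With a separate control for each hairpin r was -0.09 and -0.02. Beyond both controls by 2-fold, 665 genes were higher with hairpin A and 11 with hairpin B, 2 of them in both (CCL7 and CACHD1), where 0.491 would be met by independent lists. Lower genes numbered 646 and 8, with 5 in both, CD24 and CCN3 among them, where 0.347 would be met. In opposite directions, 2 genes were higher with hairpin A and lower with hairpin B, the near-identical heat shock genes HSPA1A and HSPA1B, where 0.357 would be met. KLHL41 alone was lower with hairpin A and higher with hairpin B (0.477 would be met). Shared controls may raise the counts in both.

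**Figure D3:**
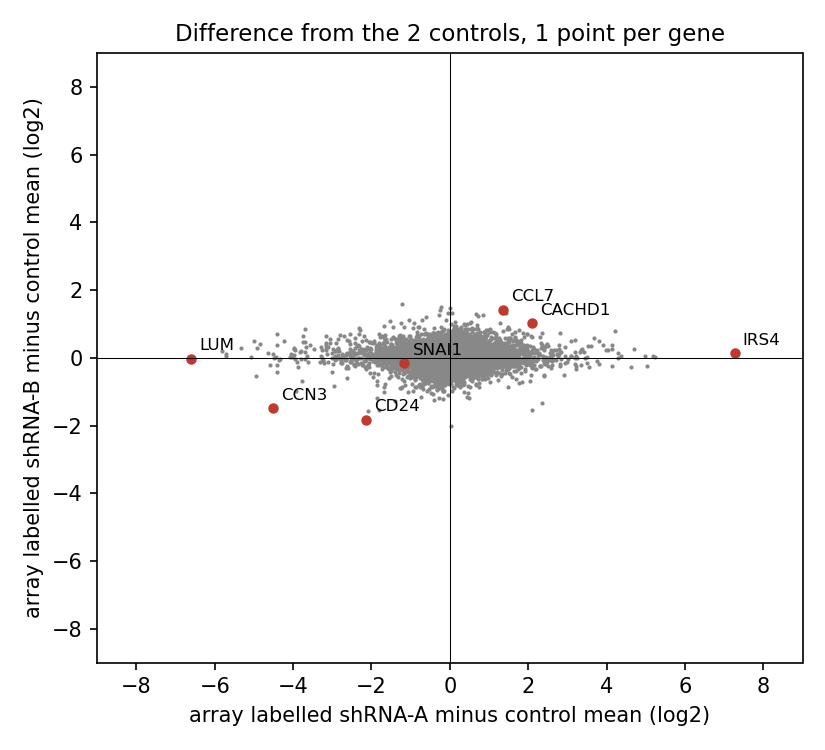
Difference from the mean of the 2 controls on the array labelled shRNA-A (horizontal axis) and the array labelled shRNA-B (vertical axis), in log2 units on equal scales, 1 point per gene. LUM (-6.59 and -0.03) and IRS4 (7.27 and 0.14) lie along the horizontal axis, while CD24 (-2.13 and -1.83) and CCN3 (-4.51 and -1.49) are low on both.

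The empty vector was compared with untreated cells, which bears on what infection, selection and culture do together, again with 1 array each and no test. GDF15, a stress-induced cytokine, was at -2.22 relative to untreated cells, GPC3 at -1.92, the stress-induced hormone FGF21 at -1.88, ENPP2 at -1.76 and TXNIP at -1.72. KLHL4 (1.70), ZNF430 (1.59), AMBN (1.53), ZNF480 (1.43) and BCL2L15 (1.27) were higher. At least 2-fold differences numbered 84, 29 higher and 55 lower. The median of the unfolded protein and amino acid response was -0.44, below all of 10000 random lists, as was that of immediate early genes (-0.29), and the G1/S median was 0.34, above all of them. The medians of these 3 lists on the array labelled shRNA-B relative to untreated cells were -0.13, 0.23 and 0.00.

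Differences were also set against the order of genes along the genome, a calculation chosen after the values were seen. Over 7439 genes above the median level the correlation of neighbouring genes' differences was 0.188 on the array labelled shRNA-A, against at most 0.0386 in 1000 shuffled orders. It was 0.060 for the array labelled shRNA-B, also beyond its shuffled orders (at most 0.0369), and 0.0305 for the empty vector against untreated cells, within them (at most 0.0436). The lowest run of 15 neighbours went from TRPS1 to NTAQ1. All 15 genes were lower on the array labelled shRNA-A, by differences from -5.33 to -0.17. The run's median was -2.64 there, against -0.000795 for the array labelled shRNA-B. Genes beyond the run, through SQLE, TRIB1 and MYC, fell as well, except FBXO32 (-0.31), which did not pass. EFR3A, the next gene above the median level, rose by 0.96. Just before the run CSMD3 was lower (-2.51), and ENY2, before CSMD3, was higher (1.08). CCN3, ENPP2, MYC, SQLE and TRPS1, named above in other groups, lie in or beside this run.

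**Figure D4:**
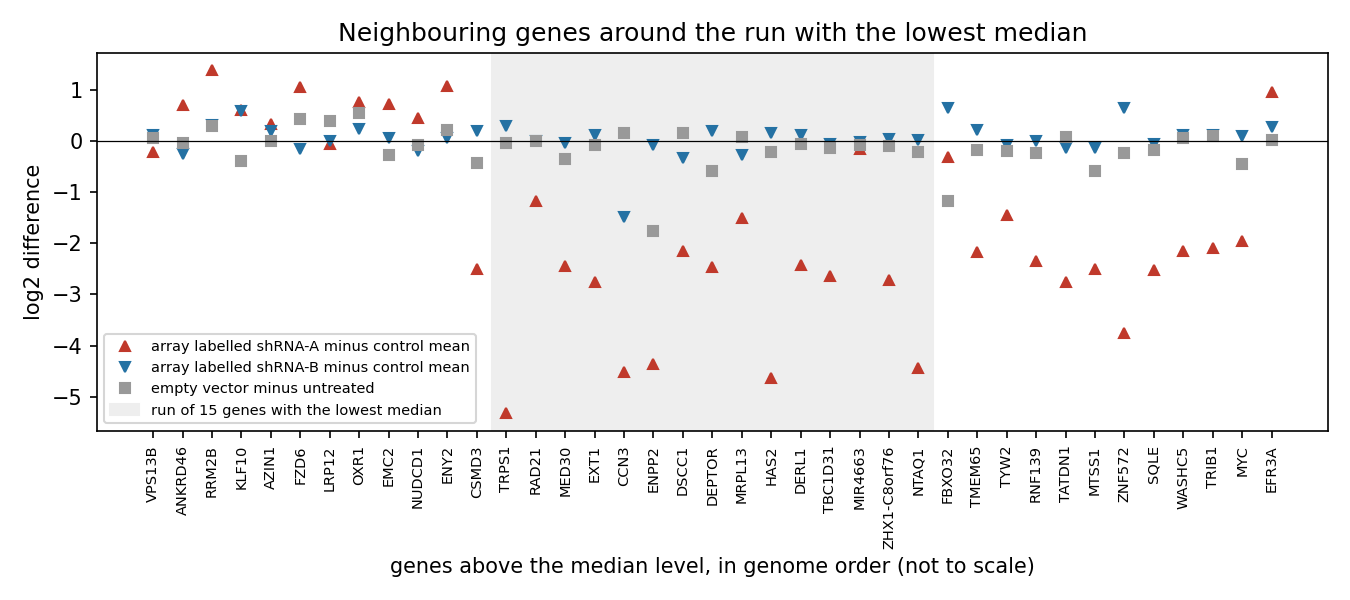
Log2 differences of neighbouring genes above the median level, in genome order and not to scale, with the 15-gene run of lowest median shaded. On the array labelled shRNA-A DERL1 lay at -2.42 and MYC at -1.96, while on the array labelled shRNA-B they lay at 0.11 and 0.10.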

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

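All tests of explanations in this part were chosen after the results were seen. Probe sets without a gene name here were not used in any comparison, and some stood above both controls by at least 1 log2. There were 17 of 37519 such probe sets for both knockdown arrays together, 728 for the array labelled shRNA-A and 111 for the array labelled shRNA-B. Those at least 1 log2 below both controls numbered 70, 1245 and 346.

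The array labelled shRNA-A stood apart from the 3 other arrays in named and unnamed probe sets. A monotone rescaling of that array's deposited values is argued against by rank correlations, which such a rescaling cannot change. The array's highest was 0.934, below the lowest of 0.987 among the others. A different treatment of its probes before they were summarized could change ranks and was not tested. RNA from cells with other DNA copy numbers, either another cell line or a subclone grown out under selection, may account for the pattern. A run of neighbouring genes had a median of -2.64, where shuffled orders reached at most 1.37 in size. Shuffling removes every tie between neighbours, shared regulation included, so such a run does not single out copy number. Of 7117 runs 26 went beyond the shuffled orders on that array, all of them lower, as its highest run median was 1.25. Neighbouring runs share all but 1 gene, so the 26 are not separate and may mark a single stretch of the genome. They do not cover the other differences on that array. For the array labelled shRNA-B, and for the empty vector against untreated cells, 0 runs did so. On the array labelled shRNA-B neighbours still correlated beyond shuffled orders at 0.060. Lower SNAI1 through hairpin A was itself not shown, as SNAI1 may differ on that array for the same reason as the other genes. It stays open as a cause of any single gene's change. SNAI1 on the array labelled shRNA-B differed from the controls by -0.16 and so offers no second test of it.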

How the results depend on the processing

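The gap count without each knockdown array was chosen after seeing the data; the other alternatives were planned. SNAI1 was lower in the knockdown group under every alternative, with -1.17 to -0.16 when 1 array was left out, and passed only without hairpin B (adjusted p = 0.017; others 0.92 to 1). Genes called by limma numbered 0 under every alternative but that one, with a range of 0 to 2024 when 1 array was left out. List calls numbered 0 with an estimated correlation, 0 with fry and 2 to 6 with 1 array left out. Without hairpin A, the G1/S list turned lower (adjusted p = 0.00831) and the unfolded protein response turned higher with no call (0.698). Their adjusted p ranged from 0.00831 to 0.409 and from 0.000208 to 0.756 with 1 array left out. Genes with a gap of 1 log2 numbered 3 of the 7 among genes above the median level, where fewer genes were tested, 49 at a gap of 1.5-fold, and 19 to 1311 with 1 knockdown array alone. Genes differing 2-fold between vector and untreated cells numbered 30 instead of 84 above the median level. The hairpins' correlation of 0.14 was 0.13 after repeated quantile normalization and 0.0399 above the median level; the cause was not tested. With a replicate block 0 genes were called and SNAI1 differed by -0.67 (adjusted p = 0.997). Same-numbered arrays' deviations correlated at -0.0797 across genes. The knockdown arrays differed from each other far more (SD across genes 0.75) than the controls did (0.29). A shared effect of the numbers could be hidden by that, so whether the numbers pair the samples was not settled. Of 1455 values of 136 named genes, 81 passed the test, all without hairpin B. Of 363 list values 11 lost a call, 7 gained one and 2 reversed. A change of sign with no call on either side was counted as no change, as for 45 gene and 33 list values. Low signal limits CCL7 and other genes under the median level.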

Other observations

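All tests of explanations in this part, and the genes named in it, were chosen after the results were seen. On the array labelled shRNA-A 10 genes were at 7 or above while under 4 on the 3 other arrays, and 14 were under 4 there while at 7 or above elsewhere. No gene of either kind was found for any other array. The first kind included the desmosomal cadherin gene DSC3 (7.06 against at most 2.56) and the neuronal hydrolase gene UCHL1 (7.02 against at most 3.42). The second included the extracellular matrix genes OGN (3.42 against 7.91 to 8.92) and MFAP4 (3.69 against 8.16 to 8.30), and the adhesion gene VCAM1 (3.09 against 7.26 to 7.82).

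The packaging cells of the 293T line, used to make the virus, are 1 candidate source of the RNA on the array labelled shRNA-A. Of 14 markers written down for this line 9 were measured, and 7 differed by at least 1 log2 in the direction written, including IRS4 (8.85 on that array), LIN28B (8.90) and UCHL1 (7.02). The kidney developmental gene PAX2, at 4.65, and SALL2, at 5.68, did not. Most of these values had been seen when the list was written, and of the 2 that had not, 1 (BEX3, 1.09) went the way written, so the source cannot be told apart from another line or a subclone.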
